A study of Xenopus laevis with 4 samples.

How the data were processed

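The series holds 4 libraries from Xenopus laevis animal caps, 1 each of control morpholino input, FTO morpholino input, control morpholino m6A-IP and FTO morpholino m6A-IP. Per the labels' protocols, polyA RNA was fragmented to about 200 nt, incubated with a polyclonal anti-m6A antibody, eluted with free m6A, made into libraries with a stranded RNA-seq kit and sequenced on an Illumina MiSeq. The deposited files hold signal, the read coverage at every base of 14 whole gene spans, introns included, with the position counted within the gene. The authors' values are whole numbers and were not scaled to library size. Per the submitters' processing notes, Bowtie2 2.2.6, SAMtools 1.8 and bedtools 2.26 were used. Their roles and settings, the genome build, the read pairing, the use of strand and the treatment of duplicates and of reads that map to both homeologs are not given in the sources used here. Coordinates are those of the files, and the 14 gene symbols were taken from the files' own annotation. Positions were read from the lowest coordinate upward; in 5 of the 7 genes on the minus strand the longest covered segment lay in the lower part of the span, which is the 3' end under this reading.

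Depth was turned into reads by counting each rise in depth as that many read starts. Of 426 isolated runs of depth 1, 196 were 66 bases long, the most frequent length in each library. A read that starts on the base after another ends is missed, so the counts are minimums. In 100 simulated data sets on the 14 spans, 95.2% of the simulated reads were recovered as read starts, and 96.5% of the intervals of the enrichment difference held the true value. In these simulations the interval of the input ratio left out 1 in 93.0% of runs when foxj1.S had been reduced to 0.4 of its control input level. Simulated reads were drawn independently, with no copies of reads added and with a known scaling. Simulated FTO libraries had the control depth apart from the changes set, whereas the observed inputs held 1205 (FTO) and 1822 (control) read starts. These rates therefore hold for the simulated settings and can overstate those for the observed data. Reads that share a start can be copies of 1 molecule or mates of a pair, and the files carry no molecular identifiers. Distinct start positions made up 68.3% of read starts in the control input, 70.0% in the FTO input, 57.6% in the control m6A-IP and 56.9% in the FTO m6A-IP. Intervals and floors cover counting error only, so each ratio was also computed with every start position counted once, an alternative chosen after the data were seen. If reads were paired, mates with different starts would count as separate reads under either count. The intervals would then be too narrow.

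Summed depths over the 14 genes were 112401 in the control input, 74605 in the FTO input, 147306 in the control m6A-IP and 80729 in the FTO m6A-IP. These are totals of a panel, not library depths, which are not given in the sources used here. A floor of 3 reads corresponds to 0.165%, 0.249%, 0.128% and 0.228% of the read starts of those libraries. Depth was scaled by the mean of the 4 panel totals over the library's own, and reads by the same rule on read starts or on distinct starts. A change of most of the 14 genes together cannot be seen on this scale.

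The comparisons were fixed before the data were examined and assumed transcripts across the transcriptome, whereas the files hold gene spans. Some choices were therefore changed or added after the data were seen. The mean depth was taken over bases covered in any library, ratios of counted reads without a pseudocount were added, and covered segments (gaps of up to 30 nt joined, at least 10 reads over the 4 libraries) were added to the planned windows of 100 nt. As planned, log2 ratios used scaled mean depth plus a pseudocount of 1 and genes with a mean scaled depth of at least 1, which 12 genes reached and foxn2.S and myb.S did not. Ratios of 2 read counts carry exact Clopper-Pearson intervals, and ratios of ratios carry exact conditional odds ratio intervals, both at 95% (scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 under Python 3.11.15). Scaling factors were treated as known. With 1 library per group no test across replicates was possible and no p-value is given.

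The rule for naming genes named foxj1 and fto, members of the ciliogenesis regulator and m6A machinery lists with an enrichment difference or input change of at least 2-fold, and, per comparison, the 10 highest and 10 lowest genes among those with a mean scaled depth of at least 10. For every other list it named the 2 highest and 2 lowest members at that depth. As 0 genes reached that depth and 0 a 2-fold value on the planned log2 scale, the rule gave foxj1.S alone, and the other 13 genes are named after their values were seen. The 15 gene lists were matched on symbol, and 8 of the 14 genes belonged to a list. The planned 10000 random lists matched on expression could not be drawn from 14 genes, so all lists of the same size within the panel were enumerated instead. The lists with 0 measured members were intraflagellar transport and basal body, m6A machinery, goblet and secretory, epidermis and keratins, mesoderm muscle and blood, neural, endoderm and notochord, ribosomal proteins, mitochondrially encoded, p53 and stress response, cell cycle, and signalling genes known to be rich in m6A. Alternatives varied the reads counted (all, distinct starts, or inside segments alone), the pseudocount, the depth filter, the scaling, the averaging over windows, and the size, fold and depth of windows.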

Results

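N6-methyladenosine (m6A) sequencing was carried out on animal cap explants of Xenopus laevis, pieces of embryonic ectoderm that develop into an epidermis with multiciliated cells when cultured. Embryos had received either a control morpholino or a morpholino against FTO, an enzyme that removes m6A from RNA. Each condition gave 1 input library of fragmented polyA RNA and 1 library of RNA recovered with an anti-m6A antibody (m6A-IP), so 4 groups held 1 library each. No group had a replicate. The series asks how FTO bears on foxj1, the transcription factor that drives motile cilium formation, and the design compares the m6A-IP with its input in each condition and both conditions with each other. Intervals below are exact 95% intervals that cover counting error between these libraries only, not the variation between embryos or explants. They are not adjusted for the 14 genes compared or for the number of segments within them.

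The data were per-base read depths over 14 whole gene spans, introns included. The genes were the transcription factors foxj1.S, rfx2.L, rfx2.S, myb.S, foxi1.S and foxn2.S, the axonemal genes dnai1.L, dnali1.S and rsph1.L, the centrosomal and centriolar genes pcm1.L, alms1.L, cep120.L and cep83.L, and ptk2.L, which encodes focal adhesion kinase. The suffixes L and S mark the long and short subgenomes of this allotetraploid frog. The control input held 1822 read starts over the 14 genes, the FTO input 1205, the control m6A-IP 2346 and the FTO m6A-IP 1317. The largest share went to pcm1.L, with 31.2% of the control input reads (29.1% to 33.4%), and the smallest to foxn2.S, with 1.26% (0.802% to 1.89%). Ratios between libraries were scaled to the 14-gene total, so a ratio of 1 is the average of this panel and not of the transcriptome. Scaling by the median of ratios instead would move every gene by 0.06 (log2) in the control IP over input ratio, by -0.15 in the FTO ratio, by -0.21 in their difference and by 0.18 in the input ratio. The fto transcript was not analysed here.

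The comparison of the m6A-IP with its input asks which transcripts the anti-m6A antibody recovered. In the control morphants, rfx2 was depleted from the m6A-IP and 4 genes were enriched, relative to the panel. Both copies of rfx2, a transcription factor of ciliary genes, were low: rfx2.L (NCBI gene identifier 108712768, chromosome 1L from 98962574 to 98990547) had an IP over input ratio of 0.301 (0.213 to 0.420, from 50 IP and 129 input reads) and rfx2.S (735210, chromosome 1S from 87311909 to 87343177) one of 0.339 (0.215 to 0.524, from 31 and 71 reads). The ratio was above 1 for dnali1.S, an inner dynein arm component, at 1.64 (1.17 to 2.34), and for foxi1.S, the ionocyte transcription factor, at 1.64 (1.21 to 2.25). It was also above 1 for cep83.L, a component of centriolar distal appendages, at 1.44 (1.11 to 1.87), and for cep120.L, a centriole elongation factor, at 1.34 (1.05 to 1.71). For foxj1.S the ratio was 0.764 (0.524 to 1.11) and for myb.S 0.854 (0.505 to 1.45), both with intervals that held 1. When each start position was counted once, rfx2.L (0.406, 0.268 to 0.604) and rfx2.S (0.381, 0.226 to 0.623) stayed below 1, whereas wider intervals that held 1 went with ratios of 1.42 for dnali1.S, 1.23 for foxi1.S, 1.32 for cep83.L and 1.21 for cep120.L.

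In the FTO morphants the same 2 rfx2 genes were low in the m6A-IP. The ratio was 0.393 (0.281 to 0.543) for rfx2.L and 0.295 (0.190 to 0.447) for rfx2.S, and foxn2.S, a forkhead transcription factor gene, was low as well at 0.380 (0.233 to 0.604) over its whole span. Of its 65 FTO input reads 38 lay outside the well covered segments, and inside them, segments being chosen on the reads of all 4 libraries with the IP included, its ratio was 0.746 (0.405 to 1.36). The ratio of dnali1.S was 2.00 (1.44 to 2.81), that of cep83.L 1.47 (1.01 to 2.18), that of cep120.L 1.46 (1.05 to 2.04) and that of ptk2.L 1.29 (1.03 to 1.62). For foxj1.S it was 1.33 (0.750 to 2.40), from 32 IP and 22 input reads. With distinct start positions, rfx2.L, rfx2.S, foxn2.S and dnali1.S kept intervals that left out 1. The ratios of cep83.L (1.32), cep120.L (1.43) and ptk2.L (1.14) then had intervals that held 1, as they did with the median of ratios at 1.32, 1.31 and 1.16. The ratio of rsph1.L, a radial spoke head gene, reached 2.53 (1.24 to 5.49) with distinct start positions, against 1.64 (0.908 to 3.04) with all reads.

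**Figure D1:**
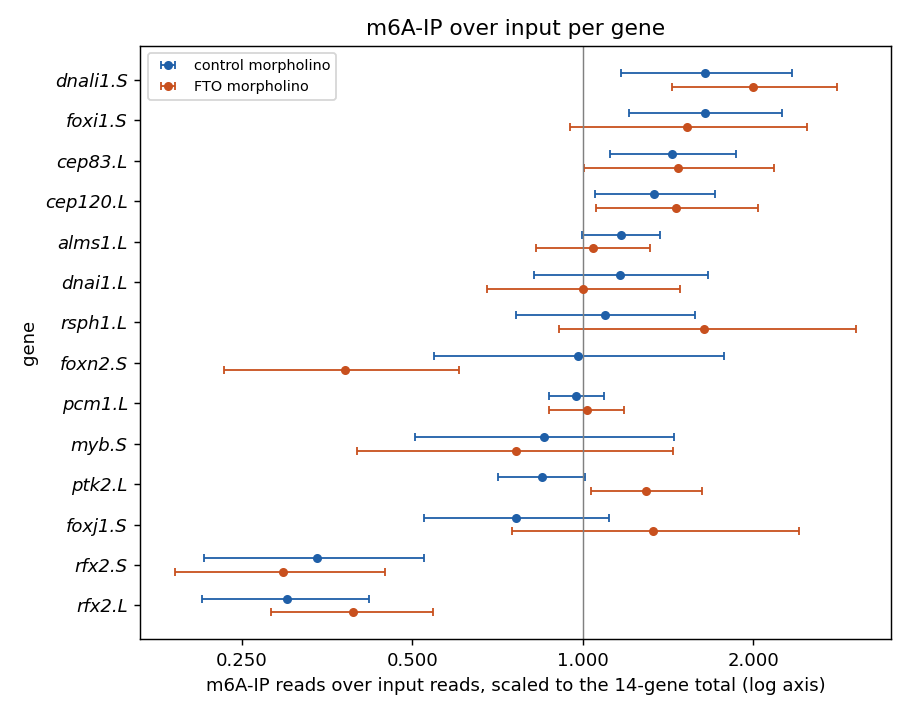
m6A-IP reads over input reads for each of the 14 genes in the control (blue) and FTO (orange) morphants, on a log axis, scaled so that 1 is the panel total; bars are exact 95% counting intervals and each point is 1 IP and 1 input library. Both rfx2 genes lie between 0.295 and 0.393, and foxj1.S lies at 0.764 in control and 1.33 in FTO morphants with overlapping intervals.

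The comparison of both conditions asks which transcripts were recovered more, or less, by the anti-m6A antibody after FTO knockdown. The IP over input ratio of foxj1.S was 1.74 times as high in FTO as in control morphants, but its interval of 0.866 to 3.53 held 1. It was the highest point estimate of the 14 genes with all reads, whereas with distinct start positions rsph1.L was higher, at 2.31 (0.982 to 5.63) against 1.88 (0.772 to 4.61) for foxj1.S, as it was with reads inside well covered segments, at 2.01 (0.829 to 5.16) against a foxj1.S interval of 0.882 to 3.69. Of the panel's m6A-IP reads, foxj1.S took 2.51% in control and 2.43% in FTO morphants, against 3.29% and 1.83% of the input reads. Its higher ratio thus came from the lower input share, and is not a finding apart from the input change of foxj1.S given below. For ptk2.L (399286, chromosome 6L from 148735508 to 148952073) the ratio of ratios was 1.53 (1.15 to 2.04) and for foxn2.S (447464, chromosome 5S from 23034559 to 23065346) 0.388 (0.180 to 0.836). These were the only 2 genes whose interval left out 1. The low value of foxn2.S went with its input share, 5.39% in FTO against 1.26% in control morphants, while its m6A-IP share was 2.05% against 1.24%. With distinct start positions ptk2.L had 1.23 (0.853 to 1.76) and foxn2.S 0.604 (0.240 to 1.53), so neither interval left out 1, and with the median of ratios ptk2.L had 1.32 (0.991 to 1.76). Inside well covered segments alone the ratio of ratios of foxn2.S was 0.411 (0.138 to 1.18), which held 1 as well, and that of ptk2.L was 1.67 (1.22 to 2.29), which left it out. The rfx2 genes had ratios of ratios of 1.31 (0.808 to 2.11) and 0.871 (0.466 to 1.63), and pcm1.L, the scaffold of centriolar satellites and the gene with the most reads, had 1.04 (0.863 to 1.26) with the panel total and 0.903 (0.746 to 1.09) with the median of ratios.

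Within foxj1.S, gene identifier 399039, on chromosome 9_10S from 33984486 to 33990266 on the minus strand, 4 segments were well covered. The m6A-IP reads of control morphants were concentrated in the segment from 33985255 to 33985784, which held 55.9% of the gene's IP reads (42.4% to 68.8%) against 15.0% of its input reads (7.10% to 26.6%). The odds of an IP read to fall in this segment rather than in the rest of the gene were 7.19 times those of an input read (2.80 to 19.4), a value that does not depend on the scaling between libraries. In FTO morphants the same segment held 37.5% of the IP reads (21.1% to 56.3%) and 9.09% of the input reads (1.12% to 29.2%), with an odds ratio whose interval ran from 1.08 to 60.2. Counting each start position once gave 7.53 (2.40 to 25.8) in control and 3.82 (0.536 to 43.6) in FTO morphants. The segment from 33988167 to 33988674, toward the 5' end, had an IP over input ratio of 0.421 (0.197 to 0.860) in control and 2.38 (0.796 to 8.52) in FTO morphants, a 5.65-fold difference (1.44 to 24.3) that rested on 5 reads in the FTO input. With distinct start positions the difference was 3.87-fold (0.689 to 23.1). This segment was 1 of 3, among 162 in the panel, whose interval of the difference lay above 1 with all reads, and 1 lay below. These intervals were not adjusted for the number of segments, and so few of 162 may leave out 1 without any difference.

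**Figure D2:**
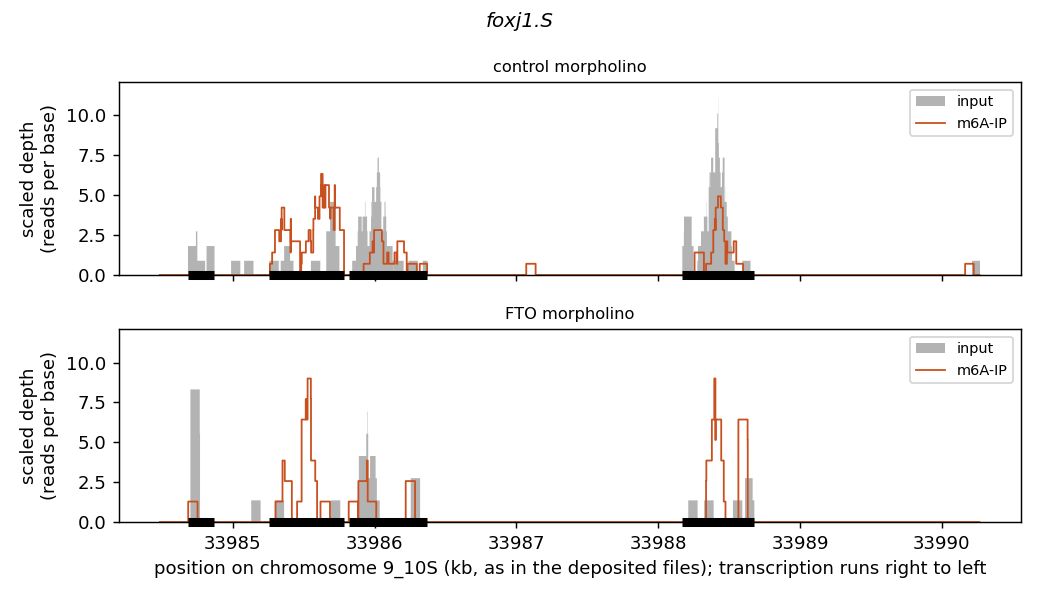
Scaled read depth per base over the foxj1.S span in control (top) and FTO morphants (bottom), input in grey and m6A-IP as an orange line; black bars mark the 4 well covered segments, and the horizontal axis is chromosome position in kb. The segment from 33985255 to 33985784 held 55.9% of the control IP reads against 15.0% of the control input reads.

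Across all 14 genes, 162 segments had at least 10 reads over the 4 libraries. A segment was called higher or lower when its share of the gene's IP reads was larger or smaller than of the input reads. The 95% interval of that odds ratio also had to leave out 1. In control morphants 20 segments were called higher and 17 lower, and in FTO morphants 16 higher and 12 lower. In both conditions 7 segments were called higher and 4 lower. Independent lists would share 2.99 and 1.24 within 4 strata of equal size by the reads of a segment. Calls in opposite directions numbered 0, although ratios could lie on different sides of 1 without a call in both conditions. The segment of rfx2.L from 98990431 to 98990547 had 4.50 (1.32 to 16.2) in control and 0.857 (0.259 to 2.48) in FTO morphants. One of the 7 lay in rfx2.L from 98965152 to 98965665 on chromosome 1L, with odds ratios of 4.21 (1.48 to 12.2) in control and 3.96 (1.63 to 9.69) in FTO morphants, although the gene as a whole was low in the IP. Another lay near the 3' end of cep120.L from 170668692 to 170668840 on chromosome 1L, with 3.14 (1.22 to 9.55) and 5.44 (1.74 to 22.4). A segment of myb.S, which encodes a regulator of multiciliated cell differentiation, from 53353415 to 53353616 on chromosome 5S held 8 IP reads in each condition and 0 input reads in either. The exact 95% lower bound of its IP over input ratio was 1.33 in control and 1.56 in FTO morphants. With distinct start positions the lower bounds of its odds ratio within the gene were 0.787 and 0.921, below 1. Counting distinct start positions, 5 segments were called higher and 7 lower in control, and 3 higher and 1 lower in FTO morphants. Of these, 0 were called the same way in both, where independent lists would share 0.2 and 0.05 within the same strata. With so few calls, that overlap of 0 says little about the overlap with all reads. The FTO to control difference left out 1 in 3 segments upward and in 1 downward with all reads, and in 0 with distinct start positions. With 162 unadjusted 95% intervals per comparison, some calls in each direction would arise without any difference. Their number was not computed. The few calls from distinct start positions and the few FTO to control differences may be no more than that.

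In the input libraries, the RNA of foxj1.S and rsph1.L made up a smaller part of the panel in FTO than in control morphants, and that of foxn2.S and both rfx2 genes a larger part. The foxj1.S ratio was 0.554 (0.324 to 0.917), from 22 FTO and 60 control reads, and the rsph1.L ratio 0.532 (0.298 to 0.912), from 19 and 54 reads. For foxn2.S, whose mean scaled depth of 0.744 lay below the planned minimum of 1, the ratio was 4.27 (2.62 to 7.21), from 65 FTO and 23 control reads. The ratio was 2.04 (1.49 to 2.82) for rfx2.S and 1.50 (1.17 to 1.93) for rfx2.L. For dnali1.S it was 1.60 (1.07 to 2.40) and for pcm1.L 0.864 (0.751 to 0.992). With distinct start positions foxj1.S (0.421, 0.215 to 0.775), rsph1.L (0.421, 0.202 to 0.815), foxn2.S (3.16, 1.84 to 5.58), rfx2.S (1.68, 1.16 to 2.43) and rfx2.L (1.49, 1.09 to 2.04) kept intervals that left out 1, and dnali1.S (1.39, 0.837 to 2.30) and pcm1.L (a log2 ratio of -0.10) did not. With the median of ratios the interval of pcm1.L, at 0.976 (0.849 to 1.12), also held 1, and the interval of foxj1.S, at 0.626 (0.366 to 1.04), and that of rsph1.L, at 0.601 (0.336 to 1.03), did so as well.

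**Figure D3:**
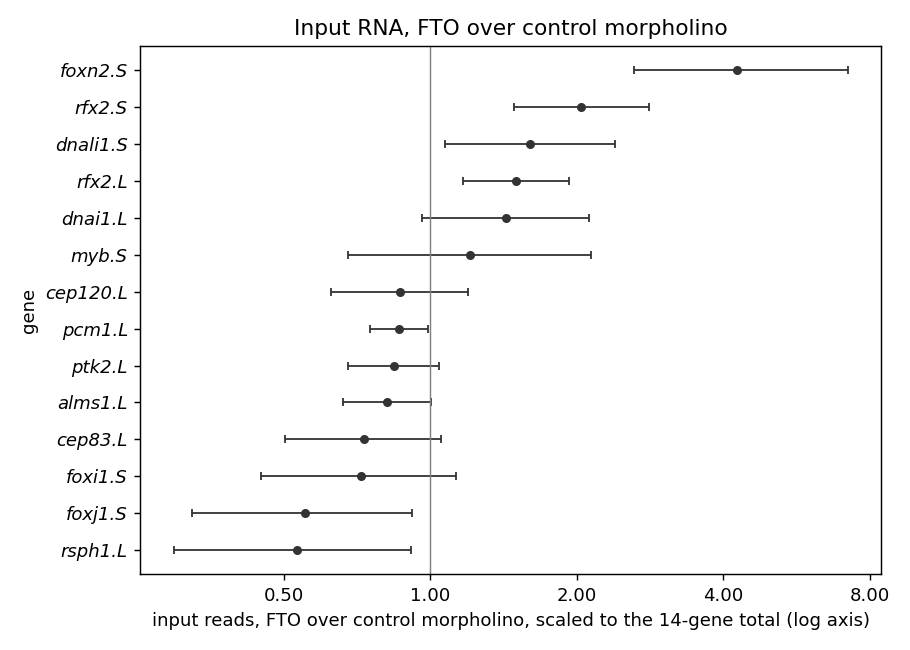
Input reads in FTO over control morphants for each gene, on a log axis, scaled to the 14-gene total; bars are exact 95% counting intervals from 1 library per condition. foxj1.S and rsph1.L lie at 0.554 and 0.532, and foxn2.S lies at 4.27, from 65 FTO and 23 control reads.

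Of the gene lists, the ciliogenesis regulators had 4 measured members (foxj1.S, rfx2.L, rfx2.S and myb.S). Their median IP over input ratio was 0.509 in control and 0.548 in FTO morphants. Of the 1001 possible lists of 4 genes from the panel, 11 had a median at or below the control value and 41 at or below the FTO value. The low medians came from the 2 rfx2 homeologs, whereas the intervals of foxj1.S (0.764 in control, 1.33 in FTO morphants) and of myb.S (0.854 and 0.762) held 1 in both conditions. Their median FTO to control ratio was 1.08 for enrichment and 1.35 for the input, and the members went different ways in the input, with foxj1.S at 0.554 and rfx2.S at 2.04. The motile cilia axoneme list had 3 measured members (dnai1.L, rsph1.L and dnali1.S), with median IP over input ratios of 1.17 in control and 1.64 in FTO morphants. Of the 364 possible lists of 3 genes, 264 had a median at or below the control value and 364 at or below the FTO value, which is that of rsph1.L, with an interval that held 1 (0.908 to 3.04). In FTO morphants dnali1.S (2.00) and rsph1.L (1.64) had the highest ratios of the panel, so every list of 3 with both ties at this median. The inputs of the 3 members also differed, at 1.43 (0.964 to 2.12) for dnai1.L, 0.532 for rsph1.L and 1.60 for dnali1.S. The ionocyte list had 1 member, foxi1.S, with an input ratio of 0.720 (0.450 to 1.13). Of the 15 lists, 12 had 0 members among the 14 genes, those of other embryonic tissues included, so markers of other tissues were not analysed here.

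On the log2 scale of scaled depth plus 1, 0 of the 12 genes with a mean scaled depth of at least 1 reached a 2-fold difference in either direction, in the IP over input ratio of either condition, in its difference or in the input. The pseudocount is close in size to the depths, so this count is set in part by the scale. The control log2 IP over input of rfx2.L was -0.80 here and -1.73 from reads without a pseudocount. Such read ratios, over 14 genes, were at least 2-fold lower for 2 genes in the control and 3 in the FTO m6A-IP, and higher for 0. The count of 0 is a matter of rounding for dnali1.S, which fell just short in the FTO m6A-IP at 1.9994. On this scale foxj1.S, with a mean scaled depth of 1.33, had log2 values of -0.22 for control IP over input, 0.23 for FTO IP over input, 0.45 for their difference and -0.48 for the input. Windows of 100 nt with at least 4-fold IP enrichment and a scaled IP depth of at least 5 numbered 6 in control and 10 in FTO morphants, of which 2 were shared, in alms1.L (7541333 to 7541432 on chromosome 1L) and foxi1.S (112865485 to 112865584 on chromosome 3S). Of the 82 windows with that depth in either IP, independent lists would share 0.732. One of the 10 lay in foxj1.S, from 33985486 to 33985585, within the segment that held 55.9% of the control IP reads. Its FTO input depth was 0, as in 4 of the 10 windows, the shared one in foxi1.S included, so the pseudocount sets the size of the fold there and none is given. Along the covered bases from the 5' to the 3' end, split into 10 equal parts, the mean log2 IP over input of the part nearest the 3' end was -0.47 ± 0.86 (SD over 12 genes) in control and -0.34 ± 1.00 in FTO morphants. The second part from the 5' end had -0.37 ± 0.74 and -0.30 ± 0.75, and the other 8 parts lay between -0.20 and 0.22 in both conditions.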

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

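The tests of counting error, scaling and read stacks in this part were chosen after the results were seen. Genes are listed here because the IP over input ratio lay on different sides of 1 in control and FTO morphants, or because the interval of the difference left out 1. Neither was tested across replicates, since each group holds 1 library.

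The ratio of foxj1.S was 0.764 in control and 1.33 in FTO morphants, a ratio of ratios of 1.74. Counting error alone may account for it, since the lower bound of the interval was 0.866. The scaling to 14 genes stays open because library totals are not given: the lowest ratio over 4 scalings was 1.48, without any scaling, and its interval held 1 as well. Stacks of reads with one start stay open too, as distinct start positions gave 1.88 with an interval of 0.772 to 4.61. The foxj1.S share of the m6A-IP was 2.51% in control and 2.43% in FTO morphants, so the ratio of ratios rested on its lower share of the FTO input. A higher m6A level of foxj1 RNA after FTO knockdown is the biological explanation the design names, and 1 library per group leaves it untested.

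The ratio of ptk2.L was 0.846 in control and 1.29 in FTO morphants, a ratio of ratios of 1.53. Its interval left out 1 with all reads and with reads inside segments (1.67, 1.22 to 2.29), and not with distinct start positions. The interval also held 1 with the median of ratios (1.32, 0.991 to 1.76) and without scaling (1.30, 0.974 to 1.73), so the scaling stays open here too. The ratio of pcm1.L was 0.973 and 1.02, a ratio of ratios of 1.04 (0.863 to 1.26) with the panel total and 0.903 with the median of ratios. The ratio of foxn2.S was 0.979 and 0.380, a ratio of ratios of 0.388, and with reads inside well covered segments alone it was 0.411 (0.138 to 1.18).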

How the results depend on the processing

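The alternatives from reads, from distinct start positions, from a panel total without pcm1.L and alms1.L, without scaling and from reads inside segments alone were chosen after seeing the data. Of the 56 read ratios (14 genes in 4 comparisons), 22 had an interval that left out 1. Counting distinct start positions moved 11 of them to intervals that held 1 and 1 the other way, the median of ratios scaling moved 7 and 2, that panel total moved 1 and 4, and reads inside segments alone moved 2, both of foxn2.S, and 5; 0 reversed. For the enrichment difference of ptk2.L, the ratio was 1.32 (0.991 to 1.76) with the median of ratios and 1.30 (0.974 to 1.73) unscaled, against 1.51 (1.13 to 2.01) with that panel total and 1.67 (1.22 to 2.29) inside segments. The counts at 2-fold were 0 in each comparison and direction with a pseudocount of 1. With a pseudocount of 0.1 there was 1 gene enriched in the FTO m6A-IP, and 2 genes were lower in the m6A-IP of each condition. The median of ratios gave 1 gene lower in the FTO m6A-IP. Read ratios without a pseudocount, over 14 genes, gave 2 genes lower in the control m6A-IP, 3 lower in the FTO m6A-IP, 1 with a lower enrichment in FTO morphants and 2 higher in the FTO input. Distinct start positions, also without a pseudocount, gave 1 enriched in the FTO m6A-IP, 1 with higher enrichment in FTO morphants (rsph1.L), 2 lower and 1 higher in the FTO input, 2 lower in the control m6A-IP and 3 lower in the FTO m6A-IP. The foxj1.S input log2 ratio of -0.48 was -0.85 from reads without a pseudocount and -1.25 from distinct start positions without one. The ciliogenesis regulators' median log2 IP over input in control was -0.61 without myb.S, which did not pass the depth filter. It became -1.35 and -0.18 with pseudocounts of 0.1 and 5, and -0.97 from reads without one and with myb.S included. In FTO morphants, -0.81, also without myb.S, became -1.28, -0.31 and, with no minimum depth, -0.49, where the addition of myb.S was the only change. The axoneme list's 0.30 in FTO morphants became 0.71 from reads and 0.83 from distinct start positions, both without a pseudocount, 0.10 with a pseudocount of 5 and 0.00 as a mean over windows. Enriched windows numbered 6 in control, 10 in FTO morphants and 2 in both. They numbered 10 and 32 at 50 nt, 0, 2 and 0 at 200 nt, 23, 26 and 7 at 2-fold, 0, 1 and 0 at 8-fold, 0, 3 and 0 at a scaled IP depth of 10, and 10 and 17 with a pseudocount of 0.1. The mean log2 IP over input at the 3' end, -0.47 in control and -0.34 in FTO morphants, was -0.30 and 0.00 with 5 parts in place of 10. Beyond the settings and members named, the cause of these differences was not tested. The foxj1.S enrichment difference stayed positive, from 0.16 to 0.91 (log2), and its log2 input ratio negative, under all alternatives run. All of these used the same libraries, and both signs rest on the low foxj1.S count in the FTO input. The constant signs are therefore not independent support. A minimum mean scaled depth of 5 left 0 genes, and the scaling without the 100 transcripts of highest depth was not run on 14 genes. Leaving out a replicate was not possible. No paired analysis was possible within a condition or for the FTO to control difference, because each group holds 1 library. A fit that pools IP against input over both conditions was not run. Read counts limit all gene values: foxj1.S had 22 reads in the FTO input.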

Other observations

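All tests in this part were chosen after the results were seen. In pcm1.L, a segment from 35412492 to 35412651 on chromosome 1L took a larger share of the gene's IP than of its input reads in both conditions, with odds ratios of 1.78 (1.07 to 3.03) in control and 4.30 (1.71 to 12.9) in FTO morphants. Another from 35439852 to 35440053 took a smaller share, at 0.332 (0.174 to 0.609) and 0.312 (0.119 to 0.742). With distinct start positions the intervals of both held 1 in both conditions. Over the 95 segments with at least 20 reads, log2 IP over input (0.5 reads added) in control and FTO morphants correlated with Pearson r = 0.49 and Spearman rho = 0.52 across segments, which are not independent replicates. Over the 50 segments with at least 40 reads they were 0.62 and 0.63. Without the rfx2 genes, the values were 0.38 and 0.43 over 85 segments with at least 20 reads, and 0.62 and 0.61 over 48 segments with at least 40. The inputs of both conditions are separate libraries, so no shared control enters these values.

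Reads outside the well covered segments made up 12.7% of the control input (11.2% to 14.3%) and 17.8% of the FTO input (15.6% to 20.0%). In the m6A-IP they made up 5.33% (4.45% to 6.32%) in control and 6.83% (5.53% to 8.33%) in FTO morphants. Segments were chosen on the summed reads of all 4 libraries, most of them IP reads, so these shares are not an independent comparison of IP with input. Of the isolated runs of flat depth, 14.3% in the control input, 23.8% in the FTO input, 27.4% in the control m6A-IP and 41.2% in the FTO m6A-IP held 2 or more reads with the same start and end.

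Both rfx2 homeologs stood below the rest of the panel in the m6A-IP of both conditions. Against the other 12 genes pooled, a ratio that needs no scaling between libraries, distinct start positions gave 0.376 and 0.354 for rfx2.L and rfx2.S in control and 0.349 and 0.285 in FTO morphants. The highest of the 4 upper bounds was 0.583, which argues against counting error and read stacks. Scaling between libraries cancels in this ratio, so it is no test of scaling. Nor can the ratio tell low recovery of rfx2 from high recovery of the other genes. The bounds are not adjusted for the choice of rfx2 after its values were seen. Inside the well covered segments alone the highest upper bound was 0.612, which argues against scattered reads as the whole cause. A low m6A content of rfx2 RNA relative to this panel is a hypothesis that stays open, as does an effect of reads shared between the homeologs, which was not tested.

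The larger share of foxn2.S in the FTO input was also weighed. Counting error and read stacks were argued against by the lower bound of 1.84 from distinct start positions. The FTO to control input ratio of reads outside segments was 1.23 (1.00 to 1.50) in the other 13 genes and 4.10 (2.17 to 8.20) in foxn2.S, which argues against a background spread over all genes. A change of foxn2 RNA with FTO knockdown, or a difference between these 2 explant pools unrelated to FTO, may account for it, and with 1 library per group these cannot be separated.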
